A study of Homo sapiens with 12 samples.

How the data were processed

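HK-2 cells were grown in a medium with growth factor, hormone and transferrin supplements, seeded on plates the day before, treated near confluence and harvested after 24 or 48 h, per the labels' protocols. Control cells received vehicle. Total RNA was extracted with a silica column kit and labelled with biotin for Affymetrix arrays, per the labels. The values used are the deposited log2 expression values of 54675 probe sets on 12 arrays, made with GCRMA per the submitters' processing notes. GCRMA subtracts a background predicted from probe sequence, normalizes arrays by quantiles and summarizes the probes of a set on a log2 scale. Its version and settings, and whether other arrays were normalized together with these 12, are not given in the sources used here. The log2 scale was taken from the values, whose highest per array lay between 16.0 and 16.2. Because such a background model pulls weak probe sets to a floor, folds of genes whose group mean lies near or below a log2 value of 4 depend on it. No detection calls were used here.

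Arrays were grouped by treatment and time as their labels give them, with 3 biological replicates per group, and no column was left unused. The probe annotation gave 1 symbol for 41091 probe sets, several for 1801 and none for 11721; 62 further probe sets were array controls. Symbols were matched through their gene identifier to a current gene table for 41043 probe sets, and 0 changed. Probe sets with several symbols or none stayed out of the main tests, and genes without a named probe set are not named in the annotation used here. There were 19775 symbols, and where a symbol had more than 1 probe set, that with the highest mean over all 12 arrays stood for the gene. Genes with a log2 value above 4 in at least 3 of the 12 arrays were kept, whatever the group, which left 10665 tested and 9110 out. Of the tested genes, 7253 had more than 1 probe set.

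A linear model of the 4 group means was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that the groups shared a single estimate of the spread. The contrasts were treated against control at 24 h, at 48 h and averaged over both times, the difference between the 48 h and 24 h effects, and control cells at 48 h against 24 h. In a treatment comparison, rose and fell mean higher and lower than in controls of the same time, unless a change with time is named. P values are two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. An exact test of single values with 3 against 3 arrays could not go below 0.1. Standard errors are those of limma, and the SD is that of the 3 arrays. The 24 gene lists covered stress responses, metabolism, cell cycle, junctions, matrix, transport and markers of nephron segments and of other cell types. List names are short labels. The list of endoplasmic reticulum (ER) chaperones also held HERPUD1 and XBP1, which are not chaperones, and that of tight junctions held the epithelial cadherin CDH1. Lists with at least 5 tested members, 21 in number, were tested with camera at a preset correlation of 0.01, adjusted over lists within a contrast. Camera with an estimated correlation and fry were run beside it. Members past the test were counted over all genes and adjusted over the list alone.

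Genes named in the text followed a rule. For 24 h and for 48 h these were the 10 largest rises and 10 largest falls among genes past the test whose 3 treated arrays all lay on the same side of all 3 controls. For the average, the difference between times and the control time course they were the 5 largest in each direction, without the condition on arrays for the difference. For the average that condition had to hold at both times, in the same direction. Up to 4 members with the smallest p of each list in each treatment comparison were added, with CDKN1A, HMOX1, NQO1, GDF15, HAVCR1 and CLDN2 whatever their values. The groups, the contrasts, the filter, the lists, this rule and the alternatives were fixed before the data were examined, except where the text says otherwise.

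The alternatives were the replicate number as a block, no filter, a floor of 6, a repeated quantile normalization, subtraction of the array median, the mean of a gene's probe sets, every probe set by itself, only the groups compared, an intensity trend with robust variance, array weights (with statmod 1.5.0), and leaving out each array in turn. Whether the replicate numbers pair the arrays was checked on deviations from group means. They correlated at 0.28 to 0.70 over the 18 pairs of the same number in different groups and at -0.45 to -0.061 over 36 pairs of different numbers, and 12 of 12 arrays had their best partner under their own number. Deviations within a group sum to 0, so positive values for the same number push those for different numbers below 0. The negative sign is thus not separate evidence. The pairing thus comes from the labels' numbers and this check, and the fit without the block stayed the reference. The fits that left out each array in turn and camera with an estimated correlation also held no block. A shift shared by a replicate number thus stayed in their residual spread. How far it accounts for the calls lost in them was not tested. The labels call the replicates biological, and nothing states what a shared number means.

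The code was tested on simulated data with 200 of 10665 genes changed. Values were drawn independently for each gene and array around the gene's mean, with its own residual spread. They held no correlation between genes and no shift shared by a replicate number. The rates and list values below thus do not cover data with either. At log2 changes of 0.5, 1 and 2 the 24 h contrast recovered 26.9, 77.6 and 100% of the changed genes, the 48 h contrast 34.3, 76.1 and 97%, the average 49.3, 88.1 and 100%, the difference between times 8.96, 58.2 and 90.9%, and the control time course 31.3, 74.6 and 100%. False calls made up 8.11, 5.48, 3.07, 2.78 and 8.67% of the calls in that order. A simulated list of 20 genes shifted by 0.5 gave a camera p of 1.49e-32, and 7 of 100 unshifted lists had a p under 0.05. The number of arrays, 3 per group, limits the precision of all values.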

Results

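Transcript levels were measured in HK-2 cells, an immortalized line of human renal proximal tubular epithelium, on 12 Affymetrix expression arrays. Cells in a hormone-supplemented medium were exposed near confluence to a low dose of Kbr, or to its vehicle, for 24 or 48 h. Each of the 4 groups held 3 biological replicates. The concentration and the full name of Kbr are not given in the sources used here. Array medians of the deposited log2 values lay between 2.91 and 2.99, and 40.0 to 40.4% of the 54675 probe sets lay above a log2 value of 4 on each array. After the filter on low values, 10665 named genes were tested. The number of arrays limits the precision of every value. Arrays of the same group correlated with Pearson's r of 0.982 to 0.993 across the tested genes, and no arrays were identical. The log2 difference between the 3′ and 5′ control probe sets of ACTB, a sign of RNA quality, was 0.794 ± 0.17 (SD, n = 3) in 24 h controls, 0.854 ± 0.11 in 24 h treated cells, 0.815 ± 0.19 in 48 h controls and 0.909 ± 0.15 in 48 h treated cells. It was higher in the treated array in 5 of 6 pairs of the same replicate number. The same difference for GAPDH ran the other way in the group means. These were -0.122 in 24 h controls and -0.143 in 24 h treated cells, and -0.0935 and -0.119 at 48 h. The first principal component of the tested genes held 48.8% of the variance. On it the 24 h controls lay at 10.1 to 26.8, the 24 h treated arrays at -8.4 to -16.1, the 48 h controls at 24.9 to 34.5 and the 48 h treated arrays at -31.8 to -38.6.

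The first comparison asked how treated cells differed from controls after 24 h. The antioxidant genes HMOX1, GCLM, NQO1 and TXNRD1 rose, and the adhesion and junction genes PPL, VCAM1 and CGN fell. HMOX1, the inducible heme oxygenase, rose 3.91-fold, from a log2 value of 8.02 ± 0.24 to 9.98 ± 0.08 (mean ± SD, n = 3; log2 change 1.97, standard error 0.21, adjusted p = 0.00168). GCLM, a subunit of the enzyme that starts glutathione synthesis, rose 3.49-fold (log2 change 1.80, standard error 0.19, adjusted p = 0.00168), and the quinone reductase NQO1 rose 2.45-fold (log2 change 1.29, standard error 0.14, adjusted p = 0.00168). The thioredoxin reductase TXNRD1 rose 2.35-fold (adjusted p = 0.00168), the ubiquitin ligase TRIM16 3.48-fold (adjusted p = 0.000288) and the vasoactive peptide gene ADM 3.74-fold (adjusted p = 0.00367). The acyltransferase GPAT3 rose by a log2 change of 1.40 and ZSCAN31 by 1.34. The other genes among the 10 largest rises were DGKG (log2 change 1.48) and CHORDC1 (1.23). PPL, which encodes the desmosomal plaque protein periplakin, was 4.67-fold lower in treated cells, going from 7.35 ± 0.33 to 5.13 ± 0.13 (n = 3; log2 change -2.22, standard error 0.17, adjusted p = 0.000288). The adhesion molecule VCAM1 was 4.50-fold lower (log2 change -2.17, adjusted p = 0.00168), DISP2 3.97-fold lower (adjusted p = 0.00302) and CGN, the tight junction protein cingulin, 3.34-fold lower (log2 change -1.74, adjusted p = 0.00775). The mean of DISP2 in treated cells, 3.27, lay below the filter floor, so its fold depends on the background correction. The remaining 6 largest falls were SCEL (log2 change -2.20), the water and glycerol channel AQP3 (-2.16), the thioredoxin-binding protein TXNIP (-2.11), ENDOD1 (-1.98), DIPK1B (-1.78) and the epithelial cadherin CDH1 (-1.75). In all of these genes the 3 treated arrays lay on the same side of all 3 controls.

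Altogether 612 genes, 5.74% of those tested, passed at 24 h: 265 were higher and 347 lower, and 114 of them differed at least 2-fold, 22 higher and 92 lower. Treated and control arrays did not overlap in any of the 612; over all genes they did not overlap in 31.8%, where chance gives 10%. With the replicate number as a block the count was 2602, 1112 higher and 1490 lower. The count rested on 5 of the 24 h arrays: 240, 141 and 158 genes passed without treated replicates 1, 2 and 3, and 81 and 177 without control replicates 1 and 2. Of the 10 largest rises 8 passed in all 12 fits that left out 1 array, as did PPL, VCAM1, DISP2 and CGN. CHORDC1 was lost without control replicate 1 (adjusted p = 0.0511), and DGKG and AQP3 without any treated 24 h array or without control replicate 1 or 2 (adjusted p up to 0.136 and 0.119). SCEL was lost without treated replicate 3 or control replicate 1 or 2 (up to 0.064), ENDOD1 without replicate 2 of either group (up to 0.0609), and DIPK1B without treated replicate 2 or control replicate 1 or 2 (up to 0.0689). CDH1 kept its call in 5 of the 12 fits (adjusted p up to 0.108; lost without treated replicate 1 or 2 or any control at 24 h, or replicate 2 of either group at 48 h). TXNIP kept its call in 2 of the fits, those without control replicate 1 or 3 at 48 h (adjusted p up to 0.136 in the others).

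Among the gene lists at 24 h, targets of NRF2, a transcription factor that drives antioxidant genes, were higher as a group. Of 23 tested members 8 rose, HMOX1, GCLM, NQO1 and TXNRD1 among them, 1 fell and 14 did not pass; adjusted over the list alone, 14 rose and 1 fell. The member that fell was the organic anion transporter ABCC3 (log2 change -0.93), named after its value was seen. The list's median log2 change was 0.61 (camera adjusted p = 7.18e-11, and adjusted p = 0.0224 with an estimated correlation). Heat shock chaperones were also higher: 6 of 10 members rose and none fell (8 adjusted over the list alone), with a median log2 change of 0.61 (adjusted p = 4.94e-07, and adjusted p = 0.0921 with an estimated correlation). HSPH1 rose by a log2 change of 1.05 (adjusted p = 0.00367), BAG3 by 0.82 and DNAJA1 by 0.74. Of 20 mitosis genes 3 rose, CCNB1 (0.62), UBE2C (0.65) and TOP2A (0.44), and none fell (10 rose adjusted over the list alone). Their median log2 change was 0.37 (adjusted p = 2.05e-07, and adjusted p = 0.363 with an estimated correlation). BAG3 (up to 0.0714), CCNB1 (0.111), UBE2C (0.139) and TOP2A (0.177) lost their calls without any treated 24 h array or without control replicate 1 or 2 at 24 h, as did UBE2C and TOP2A without treated replicate 2 at 48 h, and TOP2A without control replicate 2 or 3 at 48 h. DNAJA1 was lost without treated replicate 2 or 3 or control replicate 1 or 2 at 24 h (up to 0.0899). With the replicate block 16 NRF2 targets rose and 1 fell, and 13 mitosis genes rose.

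Of 11 members of the tight junction list, which also held the epithelial cadherin CDH1, 3 fell at 24 h: CGN, CDH1 and TJP3 (-1.45). None rose (5 fell adjusted over the list alone). The median log2 change was -0.70 (adjusted p = 0.00131, and adjusted p = 0.0921 with an estimated correlation). No gene of sterol synthesis passed over all genes, while 4 of 17 fell adjusted over the list alone. The median was -0.30 (adjusted p = 0.00114, and adjusted p = 0.248 with an estimated correlation). LSS stood at -0.52 and FDPS at -0.35, both with an adjusted p of 0.0537. Of 8 metallothionein list members, whose near-identical sequences can share probe signal, 1 fell, MT1E (-0.34), and 6 fell adjusted over the list alone. The median was -0.33 (adjusted p = 0.00159, and adjusted p = 0.532 with an estimated correlation). None of 15 genes of extracellular matrix and TGF-beta signalling passed, over all genes or adjusted over the list alone, although the list median was -0.40 (adjusted p = 0.0112, and adjusted p = 0.562 with an estimated correlation). That list was lost without treated replicate 2 (0.125) or control replicate 1 (0.081) or 3 (0.0691) at 24 h. Of 12 tubular injury markers VCAM1 and KRT19 (-0.85) fell and none rose (3 fell adjusted over the list alone), with a median of -0.16 (adjusted p = 0.0176, and adjusted p = 0.3 with an estimated correlation). This call was lost without treated replicate 1 (0.0558) or control replicate 3 (0.0953). With the replicate block 8 sterol synthesis genes fell over all genes, LSS (adjusted p = 0.00376) and FDPS (0.00832) among them, and 8 matrix and TGF-beta genes fell, among them COL4A1 (log2 change -0.52, adjusted p = 0.0639, 0.00273 with the block) and COL4A2 (-0.58, 0.109, 0.0015 with the block). The block also gave 7 metallothioneins, 6 tight junction genes and 4 tubular injury markers that fell. Among members, TJP3 passed in 3 of the 12 fits that left out 1 array, without treated replicate 1 at 24 h or treated replicate 1 or 3 at 48 h (up to 0.159 in the others). MT1E also passed in 3, without treated replicate 3 or control replicate 1 or 2 at 48 h (up to 0.151 in the others), while KRT19 was lost without any 24 h array (up to 0.131). CDH1 was lost without 7 of the arrays (up to 0.108). COL1A1, a fibroblast marker, moved alongside these matrix and adhesion genes at 24 h, with a log2 change of -1.30 (adjusted p = 0.00889).

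The other lists did not pass at 24 h. Among 21 p53 targets 2 rose, MDM2 (0.58) and AEN (0.62), and 3 fell, among them DDB2 (-1.11, adjusted p = 0.0038) and TP53I3 (-0.52). The list median was 0.10 (adjusted p = 0.569), and adjusted over the list alone 5 rose and 3 fell. CDKN1A, which encodes the cell cycle inhibitor p21, had a log2 change of 0.64 (adjusted p = 0.0509; 0.0134 with the replicate block), GDF15 of 0.86 (0.0588; 0.024 with the block), CLDN2 of -0.82 (0.0598; 0.0257 with the block) and the kidney injury marker HAVCR1 of -0.53 (0.0618; 0.00683 with the block). Of 18 DNA repair genes only the glycosylase NEIL3 passed, with a rise of 1.13 (adjusted p = 0.00394; list adjusted p = 0.77). Among 18 ATF4 targets ATF4 rose by 0.40 (list adjusted p = 0.168; 2 rose adjusted over the list alone). IFIT3 (0.58) was the interferon gene that rose (list adjusted p = 0.147, and 0.0499 without treated replicate 1 or 0.0292 without control replicate 2), DUSP5 (0.85) the immediate early gene (0.975; 2 rose and 2 fell adjusted over the list alone), ADM the hypoxia gene (0.142), and SLC3A1 (-1.34) the proximal tubule marker that fell (0.253; 1 rose and 2 fell adjusted over the list alone). No member passed among other antioxidant enzymes (list adjusted p = 0.861), endoplasmic reticulum (ER) chaperones (0.975), DNA replication genes (0.168), inflammatory cytokines (0.975), respiratory chain genes (0.194) or sodium, potassium and chloride transporters (0.975). Median, mean and test differed in sign for ER chaperones (-0.06, -0.03, up), inflammatory cytokines (0.06, -0.02, up) and immediate early genes (-0.02, 0.02, up). The sign of the median for ER chaperones, immediate early genes and the ion transporters turned under another scaling. With the replicate block, members passed in most of these lists: 5 p53 targets rose and 3 fell, 3 ATF4 targets rose and 2 fell, 1 DNA repair gene rose and 3 fell, and 5 DNA replication genes and 2 respiratory chain genes fell. It also gave 3 interferon and 2 hypoxia genes that rose, 1 proximal tubule marker that rose and 2 that fell, 2 ion transport genes that rose and 1 that fell, and 2 members each way among other antioxidant enzymes and immediate early genes, while no ER chaperone or inflammatory cytokine passed. Of the 41 genes named by the rule that passed at 24 h, 16 passed in every fit that left out 1 array and 25 were lost in some. Without a filter 13 of the 41 lost their calls, as did 13 with only the groups compared. The fits without treated replicates 1, 2 and 3 at 24 h lost 18, 23 and 19 of them, and those without control replicates 1, 2 and 3 lost 24, 24 and 6. Those without treated replicates 1, 2 and 3 at 48 h lost 4, 10 and 2, and those without control replicates 1, 2 and 3 at 48 h lost 3, 6 and 4.

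**Figure D1:**
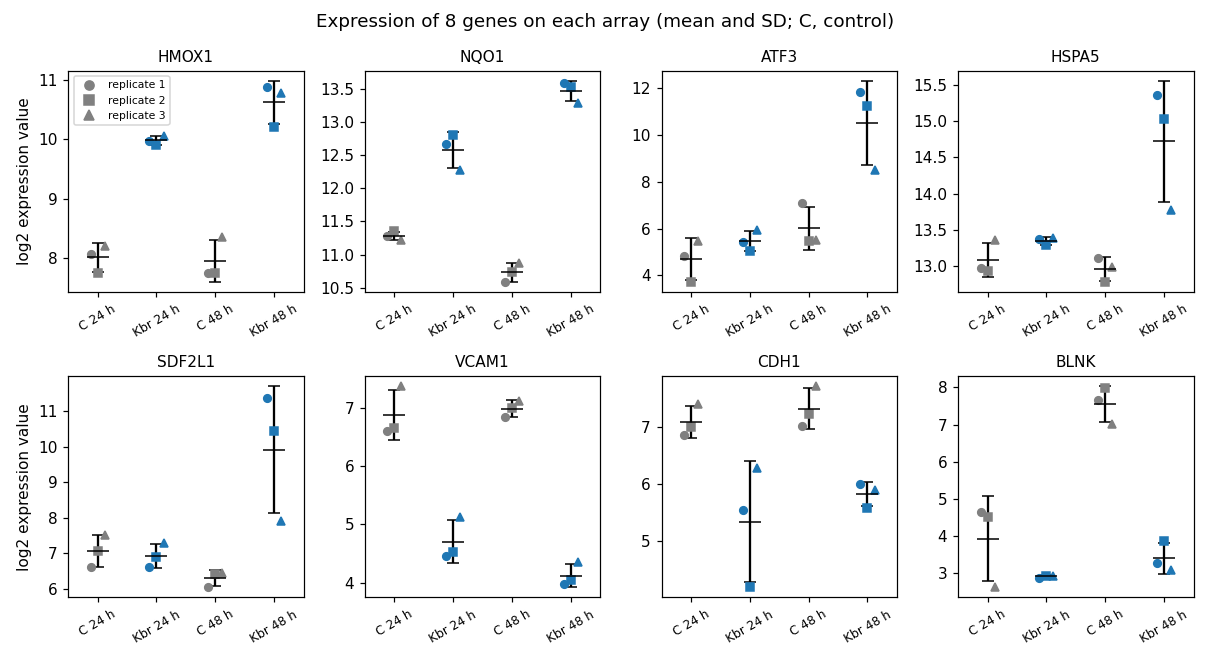
Log2 expression value (vertical axis) of HMOX1, NQO1, ATF3, HSPA5, SDF2L1, VCAM1, CDH1 and BLNK on each of the 12 arrays, by group, with symbols for the replicate number and the mean and SD (n = 3) per group. Treated arrays of HMOX1 and NQO1 lie above all controls at both times, while ATF3 at 48 h spreads with an SD of 1.79 around 10.53.

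The same comparison was made after 48 h, where the largest changes were a rise of ATF3 and lower levels of BLNK and EFEMP1 than in controls. ATF3, a stress-induced transcription factor, rose 22.8-fold, from 6.02 ± 0.92 to 10.53 ± 1.79 (mean ± SD, n = 3; log2 change 4.51, standard error 0.79, adjusted p = 0.00122). SDF2L1, an ER protein, rose 12.3-fold, from 6.29 ± 0.22 to 9.92 ± 1.80 (log2 change 3.62, adjusted p = 0.00164), and DDIT3, which encodes the transcription factor CHOP, rose 7.17-fold (log2 change 2.84, adjusted p = 0.00362). The cystine transporter SLC7A11 rose 7.53-fold and the amino acid transporter SLC7A5 7.18-fold. ADM rose 7.83-fold (adjusted p = 3.57e-05), CLIP4 8.80-fold, RGS20 8.49-fold, LURAP1L 7.15-fold and OSGIN1, an oxidative stress-induced growth inhibitor, 6.66-fold. The largest fall against controls was that of the adaptor protein gene BLNK, at 7.55 ± 0.49 in controls and 3.41 ± 0.42 in treated cells (n = 3, log2 change -4.14, standard error 0.46, adjusted p = 0.000128). At 24 h its mean was 3.94 in controls and 2.92 in treated cells. Controls thus rose with time, while treated cells stayed below the filter floor. The matrix protein EFEMP1 was 17.2-fold lower, going from 8.49 ± 0.14 to 4.38 ± 0.21 (log2 change -4.11, adjusted p = 1.84e-06). SCEL was 14-fold lower (adjusted p = 9.01e-05), ENDOD1 10.5-fold, the ectonucleotidase ENPP3 9.16-fold, the lipoxygenase ALOX5 8.71-fold, CFAP221 8-fold and COPZ2 7.68-fold, and both DIPK1B and MOB3B had a log2 change of -2.94. MOB3B went with time from 3.60 to 5.63 in controls and from 2.49 to 2.70 in treated cells, so its treated level did not drop either. Another probe set of CFAP221 had the opposite sign. Means in treated cells lay below the filter floor for BLNK, ALOX5 (2.71), MOB3B (2.70), CFAP221 (3.22), ENDOD1 (3.69) and DIPK1B (3.59), as did the control means of CLIP4 (2.71) and OSGIN1 (2.98), so these folds depend on the background correction. All 20 genes passed in every fit that left out 1 array.

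At 48 h 4564 genes, 42.8% of those tested, passed: 2351 were higher and 2213 lower (2138 and 2398 with the array median subtracted), and 1060 differed at least 2-fold, 412 higher and 648 lower. Treated and control arrays did not overlap in 4367 of them, and in 50.9% of all genes, where chance gives 10%. All 6 genes named whatever their values passed. NQO1 rose 6.62-fold, from 10.74 ± 0.15 to 13.46 ± 0.16 (n = 3; adjusted p = 2.08e-06), HMOX1 6.35-fold (adjusted p = 2.82e-05), GDF15, a stress-induced cytokine, 4.83-fold (adjusted p = 0.000107) and CDKN1A 2.46-fold (adjusted p = 0.000258). The claudin CLDN2 was 3.71-fold lower (log2 change -1.89, adjusted p = 0.000191) and HAVCR1 1.99-fold lower (log2 change -1.0, adjusted p = 0.000553).

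NRF2 targets were again higher as a group at 48 h. Of 23 members 18 rose and 1 fell (18 and 1 adjusted over the list alone), with GCLM at a log2 change of 2.54, TXNRD1 at 1.91 and ME1 at 1.24. The median was 1.12 (adjusted p = 4.28e-08, and adjusted p = 0.0551 with an estimated correlation). ER chaperones rose in 11 of 15 members and fell in none, over all genes and adjusted over the list alone, with a median of 1.20 (adjusted p = 0.00066, and adjusted p = 0.472 with an estimated correlation). HSPA5, which encodes BiP, rose 3.42-fold (adjusted p = 0.00139) and HERPUD1 3.85-fold (adjusted p = 0.00485). In the pair of replicate 3 the median change of this list was 0.164, against 2.08 and 1.52 in replicates 1 and 2. Targets of ATF4, the transcription factor of the amino acid response, rose in 12 of 18 members and fell in none, over all genes and adjusted over the list alone, with a median of 1.10 (adjusted p = 0.00066, and adjusted p = 0.466 with an estimated correlation). Besides ATF3, DDIT3 and SLC7A5, MTHFD2 rose by a log2 change of 1.52 and SLC3A2 5.74-fold. Heat shock chaperones rose in 6 of 10 members (8 adjusted over the list alone), HSPH1 by 1.54 and BAG3 by 0.92, with a median of 0.47 (adjusted p = 0.00393, and adjusted p = 0.406 with an estimated correlation).

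Mitosis genes rose in 17 of 20 members at 48 h (18 adjusted over the list alone), with CCNB1 2.09-fold higher (adjusted p = 2e-04), AURKA at a log2 change of 0.79 and BUB1 at 0.75. The list median was 0.57 (adjusted p = 3.99e-06, and adjusted p = 0.406 with an estimated correlation). Genes of hypoxia and glycolysis rose in 6 of 17 members, over all genes and adjusted over the list alone, among them ADM, VEGFA, 4.18-fold, and the glucose transporter SLC2A1, by 1.34. The median was 0.35 (adjusted p = 0.0299, and adjusted p = 0.406 with an estimated correlation; 0.0708 without control replicate 2 at 48 h, and 0.0661 with the mean of probe sets). Metallothionein list members fell in 7 of 8 cases, over all genes and adjusted over the list alone, with MT1F at -1.20 and MT2A at -0.79. The median was -0.85 (adjusted p = 6.55e-05, and adjusted p = 0.406 with an estimated correlation). Tight junction genes fell in 7 of 11 members, over all genes and adjusted over the list alone, with CGN 5.19-fold lower, CLDN3 at -1.20 and TJP3 at -1.33 (0.0505 without treated replicate 2). The list median was -0.53 (adjusted p = 0.0247, and adjusted p = 0.406 with an estimated correlation; 0.0506 without treated replicate 3). Of 15 matrix and TGF-beta genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with LTBP2 at -1.65, COL4A2 at -1.18 and CDH2 at -0.91. The gene that rose, named after its value was seen, was CCN2 (1.38). The median was -0.52 (adjusted p = 0.0382, and adjusted p = 0.558 with an estimated correlation). The call was lost without treated replicate 2 (0.0532) or 3 (0.0629) or control replicate 1 (0.0542) or 3 (0.0605) at 48 h, and with the mean of probe sets (0.104). The replicate block gave 2 matrix genes that rose and 9 that fell. The fibroblast markers COL1A1 (-2.06), DCN (-1.69) and LUM (-1.62) fell together with these matrix genes.

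Several lists that did not pass at 48 h held genes that changed in both directions. Of 21 p53 targets 7 rose and 7 fell (7 and 8 adjusted over the list alone), GADD45A rising by 1.69 and TP53INP1 and DDB2 going down by log2 changes of -1.63 and -1.23. The list median was 0.04 (adjusted p = 0.961). Of 18 DNA repair genes 3 rose, with NEIL3 4.40-fold higher, and 4 fell, with NTHL1 at -0.81 and ERCC1 at -0.75 (list adjusted p = 0.961). Of 20 DNA replication genes 3 rose, with CDC6 4.94-fold higher, and 2 fell, GINS2 (-0.52) and CCNE1 (-0.40), the latter lost without treated replicate 1 or control replicate 2 or 3 at 48 h (up to 0.0619; list adjusted p = 0.961). Immediate early genes rose in 5 and fell in 3 of 12 members (6 and 4 adjusted over the list alone), with DUSP5 at 2.20, JUN at 1.69 and JUNB at -0.86 (0.331). Among 11 inflammatory cytokines 3 rose, among them CXCL2 (1.54) and CXCL8 (0.66), and 2 fell, CCL2 (-2.47) and IL1B (-1.70; list adjusted p = 0.922; 3 rose and 3 fell adjusted over the list alone). Other antioxidant enzymes rose in 2 and fell in 3 of 16 members, TXN at 0.82 and GPX3 at -0.94 (0.331). None of 10 interferon genes passed (0.961). In the fit with the replicate block 2 other antioxidant enzymes rose and 7 fell, and 1 interferon gene rose and 1 fell. Median, mean and test differed in sign for DNA repair (-0.03, 0.01, down), DNA replication (-0.01, 0.08, down) and interferon genes (-0.06, 0.01, down).

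Further lists leaned down at 48 h without passing. Sterol synthesis genes fell in 6 and rose in 2 of 17 members, INSIG1 at -1.05 and LSS at -0.96 (list median -0.31, adjusted p = 0.0688; 0.0466 with the replicate block and 0.0257 without control replicate 2 at 48 h). Ion transport genes were lower than in controls in 7 and higher in 1 of 15 members. The kinase SGK1 stood at -1.32 and the bicarbonate cotransporter SLC4A4 at -1.21. Controls themselves rose with time in this list, by medians of 0.399, 0.347 and 0.416 in replicates 1, 2 and 3. Treated minus control medians were -0.00657, 0.00491 and -0.0241 at 24 h and -0.242, -0.378 and -0.21 at 48 h. The lower values at 48 h thus need not be a drop in treated cells. The median of that list was -0.34 (adjusted p = 0.0635; 0.0344 with the replicate block, 0.048 without control replicate 3 at 24 h and 0.024 without control replicate 3 at 48 h). Proximal tubule markers were lower than in controls in 4 of 5 members, with SLC3A1, a subunit of the renal cystine transporter, 3.77-fold lower (list adjusted p = 0.08). Their medians also leaned up with time in controls, by 0.389, 0.327 and 0.34 in replicates 1, 2 and 3, although the list did not pass there. Tubular injury markers fell in 6 of 12 members, with VCAM1 7.25-fold lower and SOX9 at -1.14 (list adjusted p = 0.114; adjusted over the list alone 1 rose and 6 fell). Respiratory chain genes fell in 4 of 18 members (1 adjusted over the list alone), UQCRC2 by a log2 change of -0.39 (list adjusted p = 0.131), and in 7 with the replicate block. Of the 105 genes named by the rule that passed at 48 h, 97 passed in every fit that left out 1 array.

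**Figure D2:**
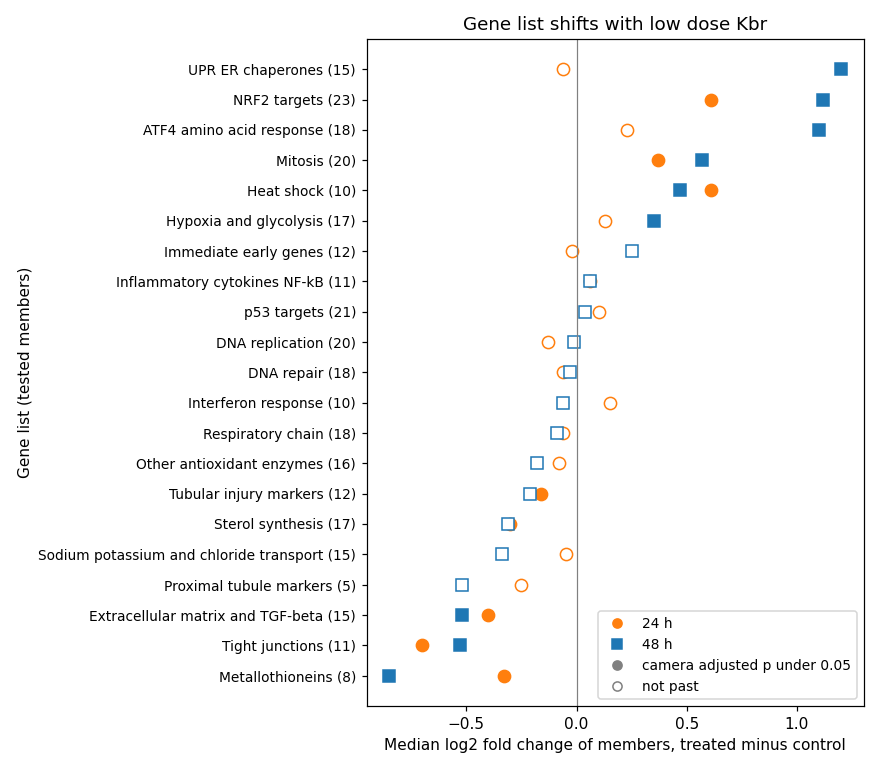
Median log2 change of treated against control cells (horizontal axis) over the tested members of each of 21 gene lists, at 24 h (circles) and 48 h (squares), with filled symbols where the camera adjusted p lay under 0.05. NRF2 targets lie at 0.61 and 1.12, ER chaperones at -0.06 and 1.20, with that sign at 24 h turning under another scaling, and metallothioneins at -0.33 and -0.85.

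The effects at both times were then set side by side. Their differences share no arrays, but both sets of calls rest on the same estimate of each gene's spread. The numbers that independent lists would share do not allow for that. Of the 265 genes higher at 24 h, 254 (95.8%) were also higher at 48 h, where independent lists would share 58.4, and of the 347 lower genes 331 (95.4%) were also lower, where 72.0 would be shared. Only 2 genes passed in opposite directions. The log2 changes correlated across genes with Pearson's r of 0.828 and Spearman's rho of 0.814; genes are not independent replicates. In 516 of the 612 genes the change was larger at 48 h, with a median ratio of 1.47. Averaged over both times, 4805 genes passed (2354 higher, 2451 lower; 2441 and 2153 with the mean of probe sets). Among those whose treated arrays lay on the same side of all controls at each time, the rises were led by ADM (log2 change 2.44, standard error 0.17, adjusted p = 1.06e-05), HMOX1 (2.32, adjusted p = 6.17e-06), TRIM16 (2.23), GCLM (2.17) and SLC7A11 (2.09). ATF3 averaged 2.64 (standard error 0.56, adjusted p = 0.0032), but its arrays overlapped at 24 h. Under the same condition, the largest falls were SCEL (-3.00), EFEMP1 (-2.81), ENDOD1 (-2.69), PPL (-2.57, standard error 0.12, adjusted p = 8.41e-07) and AQP3 (-2.52). BLNK, which overlapped at 24 h and was added after its value was seen, averaged -2.58 (adjusted p = 0.000182). The 10 genes picked under that condition passed in every fit that left out 1 array. Their same sign in all 6 pairs follows from the condition itself. NRF2 targets (19 of 23 higher, 1 lower; adjusted p = 1.06e-08, and adjusted p = 0.0445 with an estimated correlation), mitosis genes (17 higher, 19 adjusted over the list alone; 7.59e-07, and adjusted p = 0.372 with an estimated correlation), heat shock chaperones (8 higher; 0.000337, and adjusted p = 0.312 with an estimated correlation), ATF4 targets (10 higher and 1 lower, 11 and 1 adjusted over the list alone; 0.00575, and adjusted p = 0.583 with an estimated correlation) and ER chaperones (5 higher, 3 adjusted over the list alone; 0.0135, and adjusted p = 0.632 with an estimated correlation) were higher. Hypoxia genes were higher too (5 higher, 1 lower; 0.0381, and adjusted p = 0.372 with an estimated correlation), but not without treated replicate 1 (0.0545) or control replicate 2 (0.0698) at 48 h, without a filter (0.0507) or with the mean of probe sets (0.0977). Metallothioneins (7 lower; 0.000187, and adjusted p = 0.372 with an estimated correlation), tight junction genes (7 lower; 0.00797, and adjusted p = 0.291 with an estimated correlation), sterol synthesis genes (8 lower; 0.0139, and adjusted p = 0.372 with an estimated correlation) and matrix genes (7 lower and 1 higher, 8 and 1 adjusted over the list alone; 0.0162, and adjusted p = 0.583 with an estimated correlation) were lower. For the other lists that passed, the counts adjusted over the list alone were the same. In the blocked fit 8 ER chaperones were higher, and 9 hypoxia genes were higher and 1 lower. Tubular injury markers had an adjusted p of 0.0654 (0.0346 without treated replicate 3, and 0.048 without control replicate 1 or 2, at 24 h). Nor did other antioxidant enzymes (0.436), p53 targets (0.741), DNA repair (0.765), DNA replication (0.559), inflammatory cytokines (0.765), interferon (0.549), proximal tubule markers (0.112), respiratory chain (0.112), immediate early (0.54) or ion transport genes (0.176) pass.

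**Figure D3:**
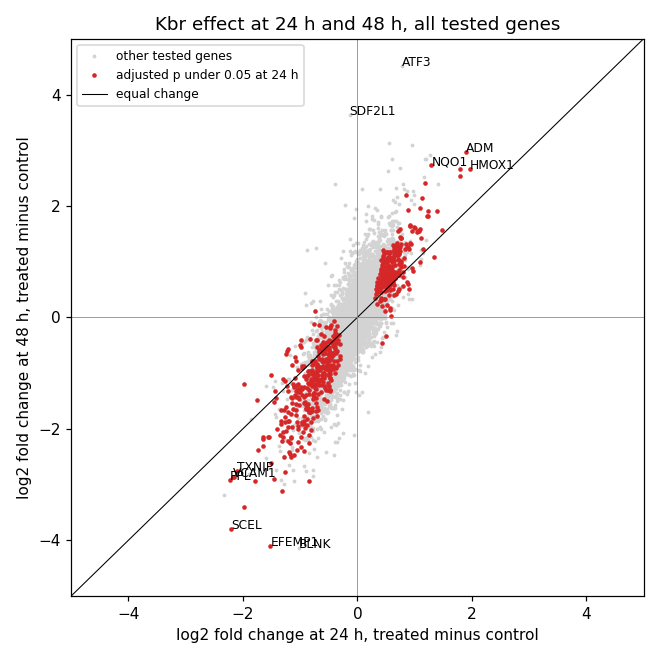
Log2 change of treated against control cells at 24 h (horizontal axis) and 48 h (vertical axis) for the 10665 tested genes, with the 612 that passed at 24 h in red and a line of equal change. Most red points lie farther from 0 at 48 h, as in 516 of the 612.

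Whether the effect itself differed between the times was tested as an interaction. The rise of NQO1 was larger at 48 h by a log2 value of 1.44 (standard error 0.20, n = 3 per group, adjusted p = 0.0269), and the fall of EFEMP1 was deeper, with a difference of -2.58 (standard error 0.27, adjusted p = 0.0129). The effect was also lower at 48 h than at 24 h for COPZ2 (-2.10), the collagen COL4A4 (-2.05), the phosphatase inhibitor PPP1R1A (-1.51) and ILDR2 (-1.40). It was higher for SEPTIN7P13 (2.21), EXOG (0.99), SCARNA15 (0.88) and TBC1D31 (0.85). A lower effect need not be a drop in treated cells: COL4A4 stood there at 3.08 and 3.05, while it rose from 3.14 to 5.16 in controls. Nor need a higher effect lie in treated cells alone. NQO1 lay at 11.22 to 11.35 in 24 h controls and at 10.59 to 10.88 in 48 h controls. In treated cells it lay at 12.27 to 12.8 at 24 h and at 13.29 to 13.58 at 48 h. In all 15 genes passed, 7 higher and 8 lower; with the array median subtracted 10 passed, 2 of them (20%) higher against 46.7%. With the replicate block 785 passed, 364 higher and 421 lower, while the block without any array numbered 3 gave 449 higher and 356 lower and array weights 188 and 120. Another probe set of EFEMP1 had the opposite sign, and the gene's call was lost without treated replicate 2 at 48 h or control replicate 3 at 24 h (up to 0.0728). None of the named genes kept its call in all 12 fits that left out 1 array: EFEMP1 kept it in 10, COL4A4 in 7 and the others in 1 to 3 (adjusted p up to 0.149). Group means of COL4A4 (3.05 to 5.16) and SEPTIN7P13 (2.97 to 5.27) reached below the filter floor. The count depended on single arrays: no gene passed without treated replicate 2 at 48 h or control replicate 3 at 24 h (limma, 1715 genes had an unadjusted p under 0.05 with all arrays), 1 to 5 passed without any other array except control replicate 3 at 48 h (15) and treated replicate 3 at 48 h (479, 315 higher and 164 lower).

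Lists whose change differed between the times were ER chaperones, with a median difference of 1.32 (adjusted p = 2.08e-06, and adjusted p = 0.478 with an estimated correlation), ATF4 targets (0.98, adjusted p = 4.53e-05, and adjusted p = 0.5 with an estimated correlation), NRF2 targets (0.50, adjusted p = 1.02e-05, and adjusted p = 0.182 with an estimated correlation) and metallothioneins (-0.55, adjusted p = 2.05e-06, and adjusted p = 0.458 with an estimated correlation). Ion transport genes (-0.23, adjusted p = 0.00365, and adjusted p = 0.458 with an estimated correlation), mitosis genes (0.24, adjusted p = 0.0107, and adjusted p = 0.738 with an estimated correlation) and hypoxia genes (0.11, adjusted p = 0.0266, and adjusted p = 0.458 with an estimated correlation) also passed. Of their members only NQO1 and SGK1 passed over all genes; adjusted over the list alone 8 ER chaperones, 4 NRF2 targets and 2 hypoxia genes were higher, 7 metallothioneins and 1 ion transport gene lower, and no ATF4 target or mitosis gene passed. With the replicate block 7 NRF2 targets and 1 hypoxia gene were higher and 7 metallothioneins and 4 ion transport genes lower over all genes. The mitosis call was lost without treated replicate 1 (0.0766) or control replicate 3 (0.181) at 24 h, or without treated replicate 3 (0.141) or control replicate 1 (0.0697) at 48 h, and with the mean of probe sets (0.109). The ion transport call was also lost with the mean of probe sets (0.0915). That of hypoxia genes was lost without treated replicate 1 (0.0597) or control replicate 2 (0.134) at 48 h, or without control replicate 1 at 24 h (0.0512). The lists that did not pass were other antioxidant enzymes (adjusted p = 0.341), p53 targets (0.872), DNA repair (0.753), heat shock (0.872), sterol synthesis (0.872), DNA replication (0.246; 0.0403 without treated replicate 1 at 48 h), inflammatory cytokines (0.872), interferon (0.165; 0.0382 without control replicate 1 at 48 h), matrix (0.29), tubular injury (0.512), tight junctions (0.487), proximal tubule markers (0.097; 0.0484 with the replicate block, 0.0305 with the mean of probe sets and 0.0258 without control replicate 3 at 48 h), respiratory chain (0.406) and immediate early genes (0.0772). Immediate early genes passed without treated replicate 3 at 24 h (0.0235), treated replicate 1 at 48 h (0.0483) or control replicate 1 at 48 h (0.0265). Median, mean and test differed in sign for p53 targets (-0.12, 0.10, down), whose sign also turned under another scaling, DNA repair (-0.02, 0.06, up), sterol synthesis (0.01, 0.04, down) and tight junctions (0.09, -0.15, down).

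Control cells at 48 h against 24 h gave the change with time in culture as a background. RAB17, a small GTPase, rose from 7.08 ± 0.13 to 9.02 ± 0.23 (n = 3; log2 change 1.94, standard error 0.13, adjusted p = 0.000103), and BLNK rose 12.2-fold, from 3.94 ± 1.14 to 7.55 ± 0.49 (adjusted p = 0.00816). COL4A4 rose by 2.02 (adjusted p = 0.000619), SLC6A13 by 2.14 and MOB3B by 2.03. TXNIP was 9.91-fold lower (log2 change -3.31, standard error 0.53, adjusted p = 0.0167), followed by the collagenase MMP1 (-3.12), SLN (-3.09), TNFAIP6 (-2.48) and TAGLN (-2.31). Means lay below the filter floor in 24 h controls for BLNK, COL4A4 (3.14) and MOB3B (3.60). In 48 h controls they did so for TNFAIP6 (3.26) and TAGLN (3.42). The folds of these genes thus depend on the background correction. In all 351 genes passed, 151 higher and 200 lower, with no overlap between groups in any of them and in 26.4% of all genes, where chance gives 10%. With the array median subtracted 282 passed, 146 of them (51.8%) higher and 136 lower, against 43% higher before. The replicate block gave 2404, 984 higher and 1420 lower. With only the groups compared 9 genes passed, and 8 of the 10 named genes lost their calls. Without a filter 185 passed, and 4 of the 10 lost theirs. BLNK, COL4A4 and RAB17 passed in every fit that left out 1 array. TXNIP was lost without control replicate 3 at 24 h (0.0679), and SLC6A13 and TNFAIP6 without that array or control replicate 1 or 2 at 48 h (up to 0.0704 and 0.0808). MMP1 was lost without those arrays or control replicate 1 at 24 h (up to 0.104), and MOB3B also without treated replicate 1 at 24 h or treated replicate 2 at 48 h (up to 0.137). SLN and TAGLN passed in 2 of the 12 fits, SLN without treated or control replicate 3 at 48 h and TAGLN without control replicate 2 at 24 h or control replicate 3 at 48 h (up to 0.208 and 0.182 in the others). Without control replicate 3 at 24 h 21 genes passed, against 99 without control replicate 1 at 24 h, 27, 34 and 558 without control replicates 1, 2 and 3 at 48 h, 153, 151 and 202 without treated replicates 1, 2 and 3 at 24 h and 153 without treated replicate 2 at 48 h.

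With time in control cells, mitosis genes fell in 11 of 20 members (all 20 adjusted over the list alone), with a median log2 change of -0.64 (adjusted p = 8.01e-15, and adjusted p = 0.237 with an estimated correlation). DNA replication genes fell in 6 of 20 members (13 adjusted over the list alone, with a median of -0.43, adjusted p = 2.74e-08, and adjusted p = 0.237 with an estimated correlation). Ion transport genes rose in 3 of 15 members (7 adjusted over the list alone, with a median of 0.35, adjusted p = 7.48e-06, and adjusted p = 0.237 with an estimated correlation). Under the replicate block 20 mitosis and 12 DNA replication genes fell, 10 ion transport genes rose, and 6 metallothioneins and 6 matrix genes fell. Smaller shifts passed for ATF4 targets (1 higher, also adjusted over the list alone, with a median of 0.25, adjusted p = 0.00827, and adjusted p = 0.691 with an estimated correlation; 0.199 without control replicate 1 at 48 h), metallothioneins (no member over all genes, 1 higher and 3 lower adjusted over the list alone, with a median of -0.26, adjusted p = 0.0352, and adjusted p = 0.691 with an estimated correlation) and matrix genes (3 lower, also adjusted over the list alone, with a median of -0.35, adjusted p = 0.0436, and adjusted p = 0.691 with an estimated correlation; 0.0543 with the replicate block). The metallothionein call was lost without control replicate 1 at 24 h (0.0851) or control replicate 2 (0.167) or 3 (0.0866) at 48 h, and the matrix call without those arrays (0.21, 0.175 and 0.0717) or treated replicate 1 at 48 h (0.05). The remaining lists did not pass: NRF2 targets (adjusted p = 0.99), other antioxidant enzymes (0.995), p53 targets (0.946), DNA repair (0.107), ER chaperones (0.946), heat shock (0.293), sterol synthesis (0.107), inflammatory cytokines (0.99), interferon (0.99), tubular injury (0.293), tight junctions (0.28), proximal tubule markers (0.0517), hypoxia (0.612), respiratory chain (0.946) and immediate early genes (0.612). Proximal tubule markers passed in 4 of the 12 fits that left out 1 array, without treated replicate 1 (0.0457) or 2 (0.0477) or control replicate 2 (0.0397) at 24 h, or control replicate 3 at 48 h (0.0304), and with the mean of probe sets (0.0148). Sterol synthesis genes passed without control replicate 3 at 24 h (0.0456) or control replicate 2 at 48 h (0.021). Median, mean and test differed in sign for NRF2 targets (0.02, 0.01, down), other antioxidant enzymes (-0.04, 0.01, down), inflammatory cytokines (0.06, -0.02, up) and ER chaperones (-0.06, 0, up). The sign of other antioxidant enzymes and inflammatory cytokines turned under another scaling.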

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

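The tests of a weaker response of all treated genes, of RNA quality and of an earlier stop of cycling in control cells, and the splits that part every pair, were chosen after the results were seen.

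The effect of Kbr differed between 24 h and 48 h, by the test of the difference itself, for 15 genes. The 48 h effect minus the 24 h effect was 2.21 (log2) for SEPTIN7P13, 1.44 for NQO1, 0.99 for EXOG, 0.88 for SCARNA15, 0.85 for TBC1D31, 0.81 for SLF1 and 0.71 for CEP43. It was -0.85 for DNPH1, -1.16 for SGK1, -1.32 for MUC1, -1.40 for ILDR2, -1.51 for PPP1R1A, -2.05 for COL4A4, -2.10 for COPZ2 and -2.58 for EFEMP1. SLF1, CEP43, DNPH1 and MUC1 lie outside the naming rule and are given because they complete the 15. COL4A4 stood at 3.14 ± 0.04 in controls and 3.08 ± 0.02 in treated cells at 24 h (n = 3), rose to 5.16 ± 0.42 in controls at 48 h and stood at 3.05 ± 0.07 in treated cells. PPP1R1A went from 7.34 ± 0.24 to 8.68 ± 0.11 in controls and from 6.93 ± 0.09 to 6.77 ± 0.26 in treated cells. No gene passed without treated replicate 2 at 48 h or control replicate 3 at 24 h, 1 to 5 passed without each other array except control replicate 3 at 48 h (15), and 479 passed without treated replicate 3 at 48 h (315 higher, 164 lower).

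Of the gene lists, 7 differed between the times: NRF2 targets (adjusted p = 1.02e-05), ER chaperones (2.08e-06), ATF4 targets (4.53e-05), metallothioneins (2.05e-06), mitosis genes (0.0107), hypoxia and glycolysis genes (0.0266) and ion transport genes (0.00365). None passed with an estimated correlation, where adjusted p lay at 0.182, 0.478, 0.5, 0.458, 0.738, 0.458 and 0.458 in that order. The mitosis call was lost without treated replicate 1 (0.0766) or control replicate 3 (0.181) at 24 h, or treated replicate 3 (0.141) or control replicate 1 (0.0697) at 48 h, and both this call and that of ion transport genes with the mean of probe sets (0.109 and 0.0915). The hypoxia call was lost without treated replicate 1 (0.0597) or control replicate 2 (0.134) at 48 h or control replicate 1 at 24 h (0.0512).

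Probe sets without a gene name, which no comparison of named genes used, also changed between treated and control cells: of 1895 tested, 31 passed at 24 h (9 higher, 22 lower) and 513 at 48 h (247 higher, 266 lower).

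The rise of ER chaperone genes at 48 h was smaller in replicate 3, with a median change of 0.164 between its treated and control arrays against 2.08 and 1.52 in replicates 1 and 2, and that of ATF4 targets was 0.509 times the mean of the other pairs. The treated array correlated with treated 24 h arrays at 0.986 to 0.989 and with the other treated 48 h arrays at 0.982 and 0.987, but on the second principal component the array numbered 3 lay highest in all 4 groups: 2.45 against -22.6 and -23.2 in treated and -3.96 against -23.2 for both others in control cells at 48 h, and 27.9 against 15.8 and 9.97 in treated and 25.8 against 11 and 3.14 in control cells at 24 h. A 24 h culture in place of that treated array is argued against by its slope of change from 24 to 48 h on that of control cells, 0.585 or 1.06 times the mean of the other pairs (0.583 and 0.517), and by a first component of -31.8, where treated 24 h arrays lay at -8.4 to -16.1. A weaker response of all treated genes is argued against by the NRF2 list, at 0.99 times the mean of the other pairs against 0.0911 for ER chaperones. RNA quality is argued against by the ACTB 3′ to 5′ difference. It exceeded the mean of the other arrays of its replicate number by 0.073, against 0.12 and 0.0715 for the treated 48 h arrays of replicates 1 and 2. A difference between cultures in the timing or strength of the ER stress response may remain as a hypothesis, and no biological explanation was tested.

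Mitosis genes rose at 48 h in 17 of 20 members (list adjusted p = 0.406 with an estimated correlation) while DNA replication genes rose in 3 and fell in 2 of 20, after both lists had fallen with time in control cells. If control cells only stopped cycling sooner than treated cells, treatment would undo a like share of the fall in both lists. The 48 h change as a share of the control fall was 0.884, 1.18 and 0.812 for mitosis genes and -0.14, 0.0435 and 0.111 for DNA replication genes in the 3 pairs, at least 0.7 apart, but it holds the difference already present at 24 h (median 0.37 and -0.13). The fall from 24 to 48 h itself was smaller in treated cells by a share of 0.392, 0.388 and 0.417 for mitosis genes and 0.207, 0.399 and 0.706 for DNA replication genes, with a largest difference of -0.29. These values do not decide, so an earlier stop of cycling in control cells and an accumulation of treated cells in G2 or mitosis, which was not tested, may each account for the pattern.

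Other splits of the arrays were counted for each comparison. Of 10 splits of the 6 arrays at 24 h, 1, the real one, gave as many genes (612, highest other 0), and likewise 1 of 10 at 48 h (4564, highest other 1), 1 of 10 for control cells over time (351, highest other 1) and 1 of 10 for the difference between times, counted on differences within pairs (894, highest other 0). These splits are too few for a share under 0.05. Every other split, here and below, also mixes the real groups, so a real difference enters the residual spread and can lower the count. The highest other counts are thus not what data without an effect would give. For the average over both times 1 of 100 drawn splits gave as many genes (4805, highest other 3557, a split that parted 4 pairs). Because the replicate numbers pair the arrays, all 32 splits that part every pair were then run, in the fit without the block. Of these 1, the real one, gave as many genes (4805, highest other 2593). A share of 1 in 32 is the smallest these splits can give, and they were chosen afterwards, so they do not exclude chance. That other split exchanged 1 pair at 24 h and kept the real groups elsewhere, so its count still holds the treatment effect of the pairs kept. Exchanging 1 pair at 48 h and keeping the real groups elsewhere gave 0 genes.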

How the results depend on the processing

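The replicate block without any array numbered 3 was chosen after seeing the data. No list call reversed, but whether more genes were higher or lower did. The cause was not tested for any change below, except that fewer arrays or genes enter some settings. At 24 h, against 612 genes, the replicate block gave 2602, array weights 1388, the block without number 3 1854, and only the groups compared 408. Leaving out 1 array gave 81 to 767 (81 without control replicate 1 at 24 h). At 48 h, against 4564, and over both times, against 4805, every probe set by itself gave 8292 and 8795 of 22368 probe sets, and leaving out 1 array gave 3641 to 4491 and 4116 to 4874. For the difference between times, against 15, the replicate block gave 785, no filter 32, a floor of 6 9, the mean of probe sets 3, array weights 308, the block without number 3 805, the array median subtracted 10, and leaving out 1 array 0 to 479 (0 without treated replicate 2 at 48 h or control replicate 3 at 24 h, 479 without treated replicate 3 at 48 h). For control cells over time, against 351, the replicate block gave 2404, no filter 185, only the groups compared 9, the block without number 3 1358, and leaving out 1 array 21 to 558 (21 without control replicate 3 at 24 h). The majority turned in these settings, given as higher and lower. At 24 h, against 265 and 347, it was 232 and 225 without a filter and 306 and 300 with the mean of probe sets. At 48 h, against 2351 and 2213, it was 2138 and 2398 with the median subtracted, 2234 and 2337 with quantile normalization repeated, 3058 and 3072 with the block, 1777 and 1787 with only the groups compared, and 1949 and 1955 without control replicate 2 at 48 h. Over both, against 2354 and 2451, it was 2304 and 2225 with a floor of 6, 2441 and 2153 with the mean of probe sets, 4628 and 4167 with every probe set, 2973 and 2969 with the block without number 3, 2203 and 2163 without treated replicate 2 at 24 h, and 2439 and 2435 without treated replicate 3 at 48 h. For the difference, against 7 and 8, it was 19 and 13 without a filter, 2 and 1 with the mean of probe sets, 188 and 120 with array weights, 449 and 356 with the block without number 3, and 315 and 164 without treated replicate 3 at 48 h. In control cells over time, against 151 and 200, it was 146 and 136 with the median subtracted, 5 and 4 with only the groups compared, 52 and 47 without control replicate 1 and 14 and 7 without control replicate 3 at 24 h, and 18 and 9 and 24 and 10 without control replicates 1 and 2 at 48 h. Lists past the test numbered 8, 9, 10, 7 and 6 at 24 h, at 48 h, over both, for the difference and for control cells over time. With an estimated correlation they were 1, 0, 1, 0 and 0, with fry 7, 15, 14, 2 and 5 (7, 9, 9, 2 and 3 of them the same lists), with the block 8, 11, 10, 8 and 5 (8, 9, 10, 7 and 5 the same), without a filter 10, 13, 11, 10 and 7 (8, 9, 9, 7 and 6 the same), with the mean of probe sets 8, 9, 9, 6 and 7 (8, 7, 9, 5 and 6 the same), and with 1 array left out 6 to 9, 7 to 10, 9 to 11, 6 to 8 and 4 to 7. Fry, which does not compare a list with other genes, ended the matrix call at 24 h (0.159), ER chaperones over both (0.101), and ATF4 targets (0.404), metallothioneins (0.137) and matrix (0.284) in control cells over time. For the difference it ended ER chaperones (0.175), ATF4 targets (0.2), mitosis (0.411), hypoxia (0.122) and ion transport (0.122). At 48 h it added sterol synthesis (0.00723), tubular injury (0.00291), proximal tubule (0.00107), and respiratory chain, immediate early and ion transport genes (0.00793 each). Over both it added tubular injury and proximal tubule (0.000778 each), respiratory chain (0.00384), immediate early (0.0457) and ion transport genes (0.0304), and in control cells DNA repair (0.00728) and proximal tubule (0.0435). The setting without a filter added DNA replication (0.00464) and respiratory chain (0.00282) at 24 h. At 48 h it added sterol synthesis (0.00837), tubular injury (0.0429), respiratory chain (0.0119) and ion transport (0.021). Over both it added tubular injury (0.016) and respiratory chain (0.00237), and in control cells DNA repair (0.0154). For the difference it added DNA replication and immediate early genes (0.0371 each) and the fibroblast, endothelial and immune markers (0.0397), a list with too few genes past the filter to be tested otherwise. The mean of probe sets added sterol synthesis (0.0461) and proximal tubule markers (0.0375) at 48 h, and proximal tubule markers for the difference (0.0305) and in control cells (0.0148). Among named genes the setting without a filter ended 13, 3, 7, 1 and 4 calls and added 1, 0, 0, 0 and 0. Only the groups compared ended 13, 5, 0, 0 and 8 and added 6, 0, 0, 0 and 0. The block added 43, 2, 5, 34 and 0 calls and ended 0. Apart from these and the calls and counts given beside their results, the block changed no other call of a list. Low signal over background limits genes whose group means lie near a log2 value of 4.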

Other observations

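The tests in this part were chosen before their results were seen, and the genes and lists are described as values. Proximal tubule markers were measured above the floor for 5 of 20 named members, DPP4 (mean log2 value 11.49 over all arrays), PAX8 (11.07), ABCC4 (10.79), ABCB1 (9.34) and SLC3A1 (8.14). Of these, ABCB1 (log2 change -0.97), ABCC4 (-0.52), DPP4 (-0.50) and SLC3A1 (-1.91) were lower than in controls at 48 h. The DPP4 call (adjusted p = 0.0457) held in 5 of the 12 fits that left out 1 array (up to 0.156), and was lost without any treated 48 h array, control replicate 1 or 2 at 48 h, or treated replicate 3 or control replicate 1 at 24 h. Of markers of other nephron segments, 3 of 14 were tested: AQP3 and SCNN1A fell at 48 h (-2.87 and -1.22), and PODXL stood at -0.34 (adjusted p = 0.211). AQP3 alone fell at 24 h, with 2 members lower adjusted over the list alone. Of fibroblast, endothelial and immune markers COL1A1 (7.69), DCN (11.53) and LUM (9.78) lay above the floor on all 12 arrays and 11 others on none. At 24 h COL1A1 and DCN fell (-1.30 and -0.73, the latter held in 3 of 12 fits, up to 0.156) and LUM stood at -0.46 (adjusted p = 0.242), and all 3 fell at 48 h (-2.06, -1.69 and -1.62). Of 4 AHR targets none passed at 24 h (1 lower with the replicate block). At 48 h NFE2L2, which encodes NRF2 itself, rose by 0.83 (adjusted p = 0.0154, and up to 0.0606 without treated replicate 1 or control replicate 2 at 48 h), and CYP1B1 stood at -0.89 (adjusted p = 0.054, 0.013 with the replicate block, past the test adjusted over the list alone).

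The 24 h treatment effect ran against the change of control cells with time: across genes the covariance was -0.0263 (Pearson's r -0.222, Spearman's rho -0.243, genes not being independent replicates). Of the 151 genes that rose with time in controls, 116 were lower in treated cells at 24 h, with a median log2 change of -0.173, and of the 200 that fell 74 were lower, with a median of 0.157. The shared 24 h control arrays argue for the opposite sign, since unchanged groups simulated against them gave covariances of 0.0164 to 0.0193, and genes near background are argued against by a covariance of -0.026 among the 6400 genes with a mean above 8. The covariances between pairs of different replicate number, which share no array, ran from -0.0525 to -0.01, below 0 in 6 of 6. They argue against shared arrays only: a slowed change with time in treated cells, and an early start of the treatment effect in genes that also change with culture age, would each give that sign, so both stay open.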
